A study of Homo sapiens with 12 samples.

How the data were processed

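RNA was measured in 12 libraries of A375 cells, a human melanoma line, 3 for each of 4 treatments: DMSO (the vehicle), the CDC7 inhibitor XL413 at 1 µM, the BRPF1/2/3 inhibitor OF1 at 1 µM, and both together, each for 24 h. Per the labels' protocols, poly(A) RNA was selected with oligo-dT beads and libraries kept strand information through dUTP in the second strand. The submitters call the libraries of a group biological replicates. Whether they came from separate cultures is not stated, so p-values measure the spread between these libraries.

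The authors deposited expected counts per gene symbol, which are estimated read counts that need not be whole and are not scaled between libraries. Bowtie2 2.1.0, RSEM 1.2.15 and the build hg38 are named in the submitters' processing notes, without settings. The gene annotation, read length and use of strand in counting are not given in the sources used here. Of the deposited values 10.6% were not whole, and they were rounded to whole numbers before any count test. The table held 26475 entries under 26473 distinct names, and 5357 entries had no count in any library. On 28 entries the name reads as a date, 2 such names stand on more than 1 entry, and none of them is named here. Total counts per library ran from 30499559 to 36062138, with a median of 33319779. Several symbols are older ones (HIST1H2AC is now H2AC6). Positions are from RefSeq on GRCh38.p14, the assembly that hg38 denotes, and were matched by symbol for 25285 names.

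edgeR 4.0.16 in R 4.3.3 was run with limma 3.58.1 and DESeq2 1.42.0 as alternatives. Genes passing filterByExpr were kept (15353), TMM factors were applied, and a quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, which left 8 residual degrees of freedom. Fold changes were tested with the quasi-likelihood F test, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The standard error is the absolute log2 fold change divided by the square root of F. The 9 comparisons were each inhibitor and the combination against DMSO, the combination against each inhibitor, the departure of the combination from the sum of the single log2 changes (non-additivity), the average effect of each inhibitor with and without the other, and any difference among the 4 groups. CPM values are counts scaled by TMM library size, with mean and SD over 3 libraries.

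Before the data were examined, 35 gene lists were fixed, of which 33 had at least 5 tested members. Lists were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, adjusted over the lists within each comparison. Each list was also tested with an estimated correlation and with fry, which asks whether a list's genes move on balance in a single direction. Counts of members that rose or fell come from edgeR over all tested genes, and again adjusted over the list alone. Lists of muscle genes were written after the data were seen.

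The genes named were set by a rule fixed in advance, except members of the muscle lists such as MYH3, ACTC1, DES and H19, chosen after their values were seen. For comparisons against DMSO it takes the 8 risen and 8 fallen genes of largest fold among those that passed, with an average log2 CPM of at least 1 and no overlap between the groups' libraries. For the comparisons with a single inhibitor it takes 5 and 5. Where no gene passed it takes the 3 of smallest p. It adds up to 3 members per list that passed, and the targets CDC7, BRPF1, BRD1 and BRPF3 with DBF4 and MCM2. Clones and pseudogenes were skipped. Some list members are left out of the text, and 1 gene that the rule takes is not reported here.

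The fits were tested on simulated data drawn from the real means and library sizes, with 200 of 15353 genes changed in 3 runs. The changed genes were taken from those with a mean of at least 1 CPM, so recovery of weaker genes was not tested. Genes were drawn independently, so genes that vary together are not represented in these runs. For XL413 against DMSO 70.2% of genes changed 1.3-fold were called, 88.1% at 1.5-fold and 95.0% at 2-fold, with 35 calls among 45375 unchanged genes. For the average XL413 effect the shares were 80.6%, 93.5% and 100%. A list raised 1.15-fold was called in 3 of 3 runs for XL413 against DMSO. The 12 pairs of replicates within groups differed by more than counting noise, with a chi-square per degree of freedom of 2.33 to 13.95, so no replicate was a copy of another of its group.

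Comparisons that share the DMSO libraries also share their chance values. For these, 20 simulations of unchanged groups gave the correlation and covariance of genes drawn independently without any effect. Genes that vary together, as muscle genes did in the real libraries, are not represented in them.

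Alternatives fixed before the data were examined were DESeq2, RLE or upper-quartile factors, no filter or a CPM of at least 1 in 3 libraries, limma-voom, the replicate number as a block, a test against a fold change of 1.2, only the 6 libraries compared, and leaving out each library. Alternatives added after seeing the data were muscle gene scores as covariates, replicate 1 alone standing for the combination (a single library, assumed to vary as the other groups do), and offsets for GC content and length (known for 96.9% of tested genes).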

Results

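Expression of 15353 genes was compared in A375 melanoma cells treated for 24 h with DMSO, XL413, OF1 or both inhibitors (the combination), with 3 libraries per treatment and 30499559 to 36062138 counts in each. XL413 inhibits CDC7, the kinase that with its partner DBF4 phosphorylates the MCM helicase when DNA replication starts. OF1 inhibits the bromodomains of BRPF1, BRD1 (also called BRPF2) and BRPF3, scaffold proteins of histone acetyltransferase complexes. The common biological coefficient of variation among replicates was 0.049.

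Skeletal muscle transcripts were present in every library and varied within groups. MYH3, an embryonic myosin heavy chain, ranged from 4.54 to 49.0 CPM over the 12 libraries, and ACTC1, a sarcomeric actin, from 7.88 to 87.4 CPM. H19, a member of the muscle progenitor list, ranged from 53.6 to 385 CPM. The mean log2 CPM of 34 muscle fibre genes was 0.35, 0.97 and 1.89 in DMSO replicates 1, 2 and 3. In XL413 it was 2.21, 1.74 and 0.88, and in OF1 1.01, 2.05 and 2.16. The combination had 0.38 in replicate 1, against -1.06 and -0.52 in replicates 2 and 3. Those last libraries also stood apart on the first principal component, which held 24.1% of the variance, at -33.4 and -31.5 against -7.0 for replicate 1. Replicate 1 in turn stood apart in the median of the list of 27 interferon-stimulated genes, which were not compared singly between replicates. The list's median log2 CPM change against DMSO was 0.39 with replicate 1 alone for the combination and 0.01 with all 3 replicates.

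**Figure D1:**
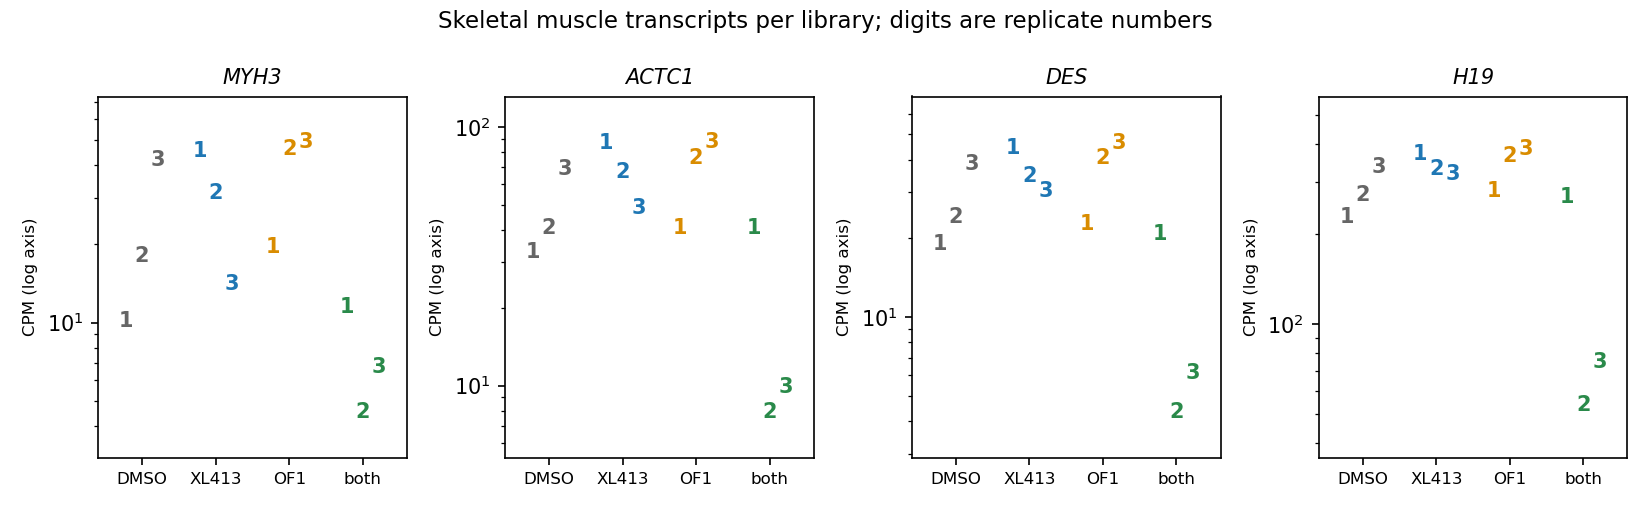
CPM on a log axis of MYH3, ACTC1, DES and H19 in each of the 12 libraries, with the replicate number as the symbol. H19 lay at 53.6 and 74.8 CPM in combination replicates 2 and 3 and at 228 CPM or more in the other libraries.

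XL413 against DMSO shows the effect of the CDC7 inhibitor alone. Of the lists tested, 13 of 28 G2/M mitotic genes, 9 of 24 NF-kB targets and secreted factors and 3 of 10 histone genes rose, and 5 of 21 ATF4 targets fell. The histone gene HIST1H2AC (chromosome 6, 26124172 to 26124690) went from 5.07 ± 0.5 to 9.4 ± 0.26 CPM (SD, n = 3 each), a 1.85-fold rise with a log2 change of 0.89 ± 0.11 (SE). CDK1 (chromosome 10, 60778331 to 60794852), the kinase that drives entry into mitosis, rose 1.36-fold from 104 ± 1.1 to 141 ± 5.5 CPM (adjusted p = 3.61e-05). CCL2, a monocyte attractant, rose 1.6-fold from 9.73 ± 0.86 to 15.6 ± 0.68 CPM. Of 28 G2/M mitotic genes 13 rose and 15 did not pass, against 15 risen and 2 fallen when adjusted over the list alone. They included HMMR (log2 change 0.57 ± 0.05) and UBE2C (0.47 ± 0.05), which serve spindle assembly and mitotic protein degradation. The list's median log2 change was 0.10 (camera adjusted p = 1.74e-07). Of 10 replication-dependent histone genes, HIST1H2AC, HIST1H2BD (0.79 ± 0.15) and HIST1H2BK (0.69 ± 0.07) rose and 7 did not pass, with 3 risen when adjusted over the list alone (median 0.37, camera adjusted p = 0.000196). Most transcripts of such genes lack a poly(A) tail, and the libraries were selected for poly(A). Of 24 NF-kB targets and secreted factors of senescent cells 9 rose and 15 did not pass, with 14 risen when adjusted over the list alone. CXCL1 rose 1.3-fold and CXCL8 1.32-fold, both neutrophil attractants (list median 0.22, camera adjusted p = 4.95e-12). Of 21 ATF4 targets of the integrated stress response 5 fell and 16 did not pass, with 11 fallen and 1 risen when adjusted over the list alone. The amino acid transporter SLC7A5 fell by 0.26 ± 0.04, and the synthesis enzymes PSAT1 and ASNS by 0.14 ± 0.03 and 0.16 ± 0.03 on the log2 scale (list median -0.12, camera adjusted p = 1.7e-05). These 4 lists kept their calls with an estimated correlation, at adjusted p of 0.00654, 0.0265, 0.00939 and 0.0482. MYC and ribosome biogenesis genes had a median of -0.08, with 4 of 22 fallen and 11 fallen when adjusted over the list alone (camera adjusted p = 2.88e-06, and adjusted p = 0.103 with an estimated correlation).

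Among single genes MCM3, a subunit of the MCM helicase, rose by 0.29 ± 0.03 on the log2 scale. The receptor kinase AXL fell by 0.37 ± 0.04 and the hexokinase HK2 by 0.23 ± 0.03. Among genes with an average log2 CPM of at least 1 and no overlap between the libraries of both groups (the better expressed genes), other large rises were those of LAPTM5, GPRC5B, MIR99AHG and DDO, at 0.61 to 0.80. The largest falls among these were those of FAM196B, BCYRN1, FDXACB1, LINC01446, ADAMTS6, MMAA, SLITRK4 and ST8SIA4, from -0.73 to -0.47. With muscle scores as covariates GPRC5B and MMAA lost their calls, at log2 changes of 0.55 and -0.48. CDC7 itself was at 23.3 ± 1.0 CPM in DMSO and 23.2 ± 1.1 CPM in XL413 (adjusted p = 0.974), and DBF4 and MCM2 did not pass. The 28 p53 targets had a median of 0.00 (camera adjusted p = 0.738). In all, 193 genes rose and 237 fell (430 of 15353; 241 and 210 with upper-quartile factors), with a median absolute log2 change of 0.22, and 6 changed more than 2-fold. Leaving out DMSO replicate 1, 2 or 3 gave 128, 92 or 120 genes, and leaving out XL413 replicate 1, 2 or 3 gave 287, 86 or 104, with 5 of the 16 better expressed genes of largest fold (HIST1H2AC, HIST1H2BK, CCL2, BCYRN1 and ADAMTS6) passing in all of these. Among the other genes above, HIST1H2BD lost its call without DMSO replicate 2 or 3 or XL413 replicate 2 or 3, PSAT1 without DMSO replicate 1 or 2 or XL413 replicate 2, and ASNS without DMSO replicate 1 or 3, while the 6 libraries alone called 1394 genes, GC and length offsets 801 and a test against a 1.2-fold change 5.

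**Figure D2:**
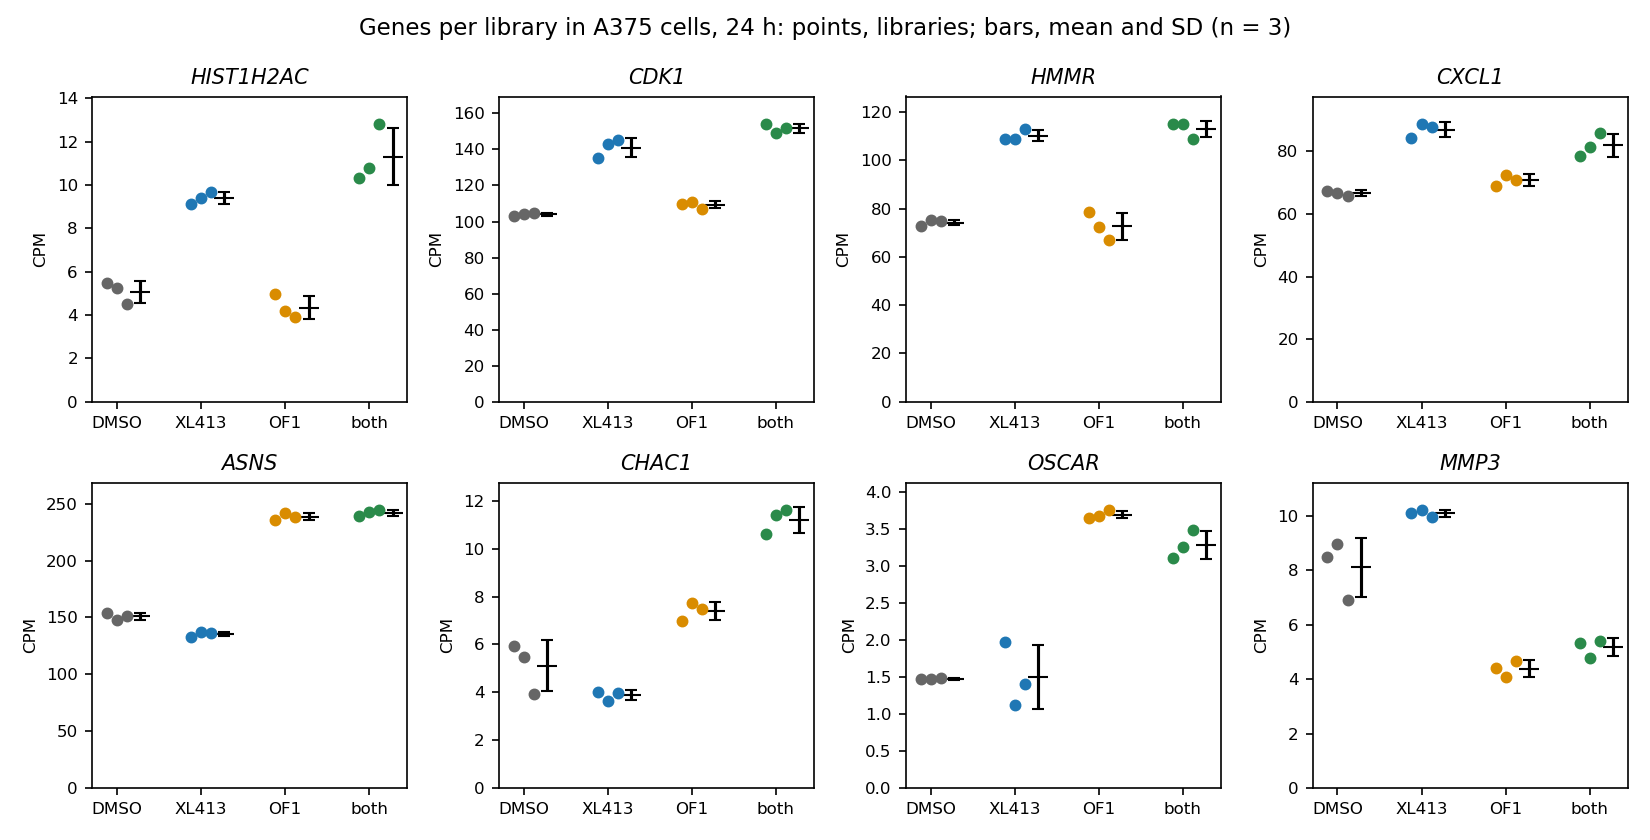
CPM of 8 genes in each library (points, n = 3 per treatment) with the mean and SD (bars), on axes from 0. HIST1H2AC, CDK1, HMMR and CXCL1 were higher with XL413, alone or with OF1, than with DMSO, and ASNS and OSCAR were higher and MMP3 lower with OF1, alone or with XL413, than with DMSO.

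OF1 against DMSO shows the effect of the bromodomain inhibitor alone. Of 21 ATF4 targets of the integrated stress response 10 rose, with amino acid enzymes among them. ASNS (asparagine synthetase, chromosome 7, 97851677 to 97928441) rose 1.58-fold from 151 ± 2.9 to 239 ± 3.2 CPM (SD, n = 3 each), with a log2 change of 0.66 ± 0.03 (SE, adjusted p = 1.19e-08). The immune receptor gene OSCAR (chromosome 19, 54094668 to 54100803) rose 2.5-fold, from 1.48 ± 0.015 to 3.69 ± 0.055 CPM. The matrix protease MMP3 (chromosome 11, 102835801 to 102843609) went from 8.12 ± 1.1 to 4.39 ± 0.31 CPM and fell by 0.89 ± 0.10 on the log2 scale. Of 21 ATF4 targets 10 rose and 11 did not pass, with 18 risen when adjusted over the list alone (median 0.21, camera adjusted p = 7.92e-18, adjusted p = 0.0035 with an estimated correlation). Among them were the serine synthesis enzyme PSAT1 (0.40 ± 0.03), the folate enzyme MTHFD2 (0.21 ± 0.03) and CHAC1 (0.53 ± 0.12), which degrades glutathione. PCK2 (0.57 ± 0.06), the cystine transporter SLC7A11 (0.51 ± 0.08), CTH (0.50 ± 0.09), the stress cytokine GDF15 (0.60 ± 0.08) and IL1A (0.66 ± 0.10) also rose. Among the better expressed genes, the largest falls besides MMP3 were those of ANKRD2, ALPP, IL18, AP1M2, DOCK2, SFN and HRCT1, from -0.82 to -0.41. CA9, a hypoxia-induced carbonic anhydrase, fell by 1.36 ± 0.26 at a low level, from 1.5 ± 0.45 to 0.585 ± 0.16 CPM. Of the 11 other lists called, cholesterol synthesis had a median of -0.08 (camera adjusted p = 0.00164, and adjusted p = 0.052 with an estimated correlation), with 5 of 20 fallen when adjusted over the list alone. Keratinocyte and epithelial markers had 2 of 10 fallen, SFN and KRT14, with 4 fallen when adjusted over the list alone (median -0.23, camera adjusted p = 0.000983, and adjusted p = 0.052 with an estimated correlation). With muscle scores as covariates IL18, HRCT1 and KRT14 lost their calls, at log2 changes of -0.57, -0.4 and -0.27. The 28 G2/M mitotic genes had a median of -0.02 and were not called (camera adjusted p = 0.114), while the kinases AURKA and PLK1 and the activator CDC20 fell by 0.14 to 0.18. BRPF1, BRD1 and BRPF3 did not pass, with log2 changes of -0.02 ± 0.04, -0.17 ± 0.06 and -0.08 ± 0.04, and MCM2 fell by 0.14 ± 0.03. In all, 89 genes rose and 87 fell (176 of 15353; 96 and 97 with upper-quartile factors). Leaving out DMSO replicate 1, 2 or 3 gave 54, 42 or 48 genes, and leaving out OF1 replicate 1, 2 or 3 gave 79, 44 or 69, with ASNS, OSCAR, IL1A, GDF15, PCK2, SLC7A11, MMP3, ALPP and DOCK2 passing in all of these among the 16 better expressed genes of largest fold. DESeq2 called 357 genes (137 risen, 220 fallen) and a test against a 1.2-fold change 5, while AURKA, PLK1, CDC20, MCM2 and KRT14 lost their calls on leaving out any library, CHAC1 on leaving out any but DMSO replicate 1, SFN without DMSO replicate 2 or 3, and CA9 without DMSO or OF1 replicate 1 or 2.

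The combination against DMSO shows both inhibitors together. Of the lists tested, 15 of 21 ATF4 targets, 16 of 28 G2/M mitotic genes and 3 of 10 histone genes rose. In lists that lost their calls with an estimated correlation, 11 of 22 matrix genes and 7 of 20 cholesterol synthesis genes fell. HIST1H2AC rose 2.23-fold to 11.3 ± 1.3 CPM (SD, n = 3), CDK1 1.46-fold to 152 ± 2.3 CPM and ASNS 1.6-fold to 242 ± 2.5 CPM. CHAC1 (chromosome 15, 40953471 to 40956512) rose 2.19-fold, from 5.11 ± 1.1 to 11.2 ± 0.55 CPM (log2 change 1.13 ± 0.12, SE). Of 28 G2/M mitotic genes 16 rose and 12 did not pass, with 16 risen and 2 fallen when adjusted over the list alone. HMMR and UBE2C both rose by 0.61 ± 0.05 (list median 0.13, camera adjusted p = 4.01e-08). Of 10 histone genes 3 rose, also when adjusted over the list alone (median 0.53, camera adjusted p = 0.000334). Of 21 ATF4 targets 15 rose and 6 did not pass, with 17 risen when adjusted over the list alone (median 0.34, camera adjusted p = 5.95e-16). Of 26 origin licensing and firing genes ORC3 (0.29 ± 0.06) and GINS3 (0.22 ± 0.06) rose, also when adjusted over the list alone (median 0.06, camera adjusted p = 0.00213). These 4 lists kept their calls with an estimated correlation, at adjusted p of 0.00258, 0.037, 0.00258 and 0.0458. The licensing list missed the threshold where replicate 1 alone stood for the combination (adjusted p = 0.0557). NF-kB targets and secreted factors had 9 risen and 2 fallen of 24, with 11 and 3 when adjusted over the list alone (median 0.15, camera adjusted p = 0.000228, and adjusted p = 0.0865 with an estimated correlation). Other large rises among the better expressed genes were those of OSCAR, HIST1H2BD, ADM2, the stress regulator NUPR1 (0.80 ± 0.08), LAPTM5 and GCOM1, a read-through transcript whose reads overlap those of its neighbours.

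Some genes of lipid synthesis fell in the combination. SREBF1, which encodes the regulator of fatty acid synthesis genes, fell by 0.49 ± 0.04 and the desaturase SCD by 0.30 ± 0.03. Of 20 cholesterol synthesis genes 7 fell, also when adjusted over the list alone, among them INSIG1 (-0.44 ± 0.06) and DHCR7 (-0.33 ± 0.05; list median -0.06, camera adjusted p = 0.00213, and adjusted p = 0.0533 with an estimated correlation). Of 12 fatty acid synthesis genes 3 fell and 1 rose, with 4 and 1 when adjusted over the list alone, and the list was not called (median -0.01, camera adjusted p = 0.0991). The melanocyte regulator MITF fell by 0.33 ± 0.05 and AXL by 0.29 ± 0.04, as single genes. On the log2 CPM scale the median was -0.03 for 13 MITF-driven differentiation genes and -0.04 for 18 genes of the invasive AXL-high state.

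Collagen and muscle genes were among the better expressed genes of largest fall in the combination. COL1A1 (chromosome 17, 50184101 to 50201631) went from 92.5 ± 11 to 33.5 ± 17 CPM and fell by 1.47 ± 0.23 on the log2 scale. COL1A2 fell by 1.39 ± 0.28 and the muscle genes MYH8, MYH7, TTN, SYNPO2 and FLNC by 1.41 to 2.18. BIVM-ERCC5, a read-through transcript that shares reads with its parts, fell by 2.26 ± 0.29. Of 22 TGF-beta and extracellular matrix genes 11 fell and 11 did not pass, with 16 fallen when adjusted over the list alone (median -0.37, camera adjusted p = 1.46e-05, and adjusted p = 0.249 with an estimated correlation). Of 12 fibroblast markers 6 fell, with 7 fallen when adjusted over the list alone (median -0.82, camera adjusted p = 9.48e-05, and adjusted p = 0.255 with an estimated correlation). With replicate 1 alone for the combination the median on the log2 CPM scale was -0.11 for matrix genes and -0.23 for fibroblast markers, against -0.38 and -0.98 on that scale with all 3 replicates. Beside these, 6 of 34 muscle fibre genes fell (median -1.52), and combination replicates 2 and 3 had the lowest muscle scores of the 12 libraries. With muscle scores as covariates, or replicate 1 alone for the combination, MYH8, MYH7, TTN, SYNPO2 and GCOM1 lost their calls, as did ADM2, COL1A2 and GINS3 with the covariates and FLNC and LAPTM5 with replicate 1 alone. With replicate 1 alone the log2 change was 0.78 for LAPTM5, 1.17 for GCOM1 and -0.50 for FLNC, and with the covariates 1.1 for GCOM1, 0.76 for ADM2, 0.29 for GINS3 and -0.68 for COL1A2. In all, 867 genes rose and 778 fell (1645 of 15353), of which 15 rose and 52 fell more than 2-fold. Leaving out DMSO replicate 2 or 3 or combination replicate 2 gave 728, 751 or 1035 genes, and MYH8, MYH7, TTN and SYNPO2 lost their calls in each of these and without combination replicate 3. The count was 421 with muscle scores as covariates, 857 with replicate 1 alone for the combination, 878 in the 6 libraries alone and 34 against a 1.2-fold change.

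**Figure D3:**
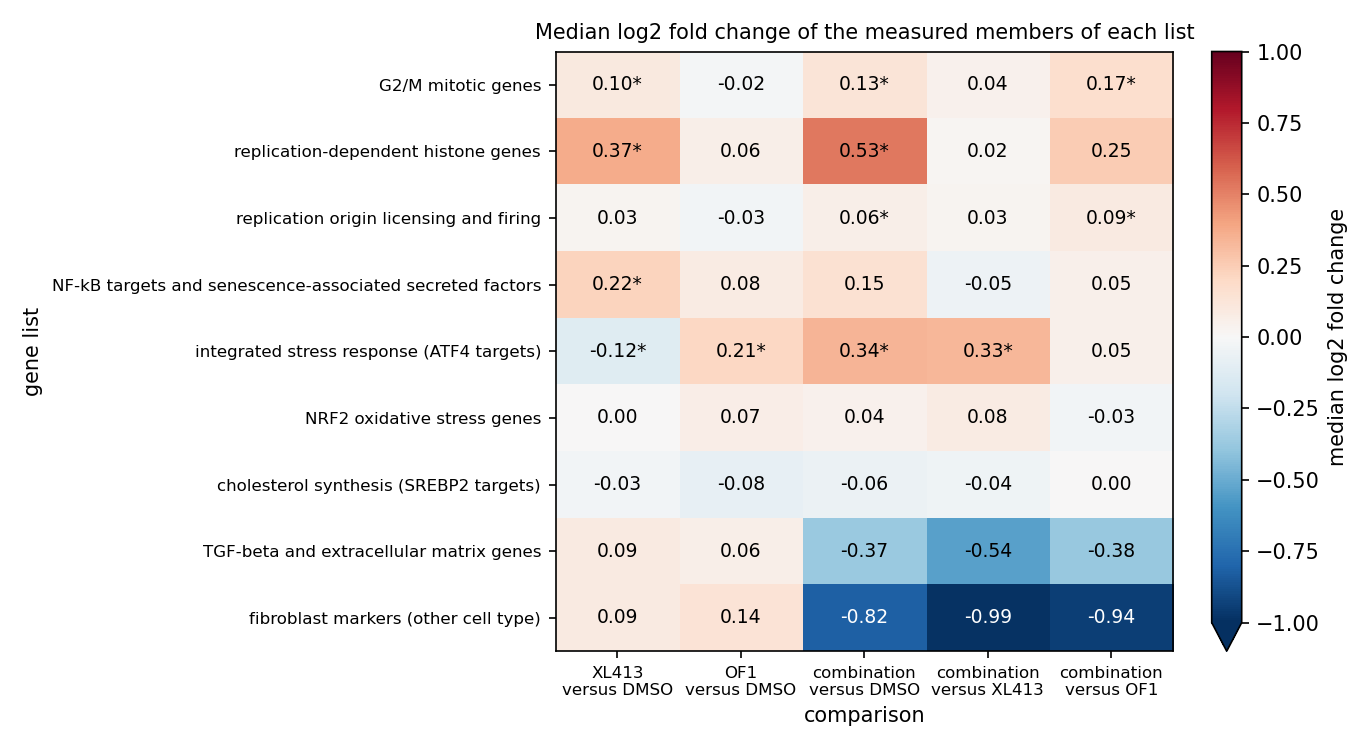
Median log2 fold change of the measured members of 9 gene lists (vertical axis) in 5 comparisons (horizontal axis), with an asterisk where the list passed with an estimated correlation. ATF4 targets lay at -0.12 with XL413, 0.21 with OF1 and 0.34 with both against DMSO, and fibroblast markers at -0.82 in the combination against DMSO.

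The combination against XL413 shows what OF1 added to cells that also had XL413. Stress response genes rose again. CHAC1 rose 2.87-fold (log2 change 1.52 ± 0.12, SE), from 3.88 ± 0.21 to 11.2 ± 0.55 CPM (SD, n = 3 each), ASNS 1.79-fold (0.84 ± 0.03, adjusted p = 4.31e-10) and NUPR1 1.78-fold. ADM2 rose 2.53-fold and OSCAR 2.18-fold. Of 21 ATF4 targets 17 rose and 4 did not pass, with 20 risen and 1 fallen when adjusted over the list alone (median 0.33, camera adjusted p = 5.58e-31, adjusted p = 0.000469 with an estimated correlation). MMP3 fell by 0.96 ± 0.10, SREBF1 by 0.40 ± 0.04 and CCL2 by 0.38 ± 0.07 on the log2 scale. Of 17 NRF2 oxidative stress genes SLC7A11 (0.71 ± 0.08), NQO1 (0.31 ± 0.04) and TXNRD1 (0.20 ± 0.03) rose, with 7 risen and 2 fallen when adjusted over the list alone (median 0.08, camera adjusted p = 0.014, and adjusted p = 0.105 with an estimated correlation). Among the better expressed genes, the largest falls were those of the muscle genes MYBPH, TNNT3, TNNI1, MYLPF and MYH8, from -2.77 to -2.50, and 20 of 34 muscle fibre genes fell. Of 22 matrix genes 15 fell, with 19 fallen when adjusted over the list alone (median -0.54, camera adjusted p = 4.74e-15, and adjusted p = 0.105 with an estimated correlation). On the log2 CPM scale their median was -0.24 with replicate 1 alone, against -0.55. In all, 163 genes rose and 361 fell (524 of 15353). The count was 39 with muscle scores as covariates, which ended the calls of ADM2, OSCAR, CCL2, NQO1, TXNRD1 and the 5 muscle genes, 155 with replicate 1 alone for the combination, which ended those of OSCAR, CCL2 and the 5 muscle genes, 812 with GC and length offsets and 33 against a 1.2-fold change. It was 191 or 197 without XL413 replicate 1 or 2, 828 without combination replicate 1 and 168 without combination replicate 2, and the 5 muscle genes lost their calls without XL413 replicate 1, XL413 replicate 2 or combination replicate 2, as did CCL2 without either of the latter, and all of them but MYLPF and CCL2 without combination replicate 3. Where their calls ended, log2 changes were 1.05 for OSCAR and -0.42 for CCL2 with replicate 1 alone, and 1.17 for OSCAR, -0.52 for CCL2, 1.19 for ADM2, 0.25 for NQO1 and 0.22 for TXNRD1 with the covariates, while the 5 muscle genes lay at -1.91 to -1.49 and -0.08 to 0.31.

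The OF1 effect could be set beside itself without a shared library, as OF1 against DMSO and the combination against XL413. Of the 176 genes called in the former, 166 (94.3%) had the same direction in the latter, against 57.7% of all genes (50.2% in simulations of unchanged groups). Both comparisons called 50 genes as risen, where independent lists would share 0.9, and 28 as fallen, where they would share 2. Across all genes, which are not independent replicates, Pearson's r was -0.04 and Spearman's rho 0.18.

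The combination against OF1 shows what XL413 added to cells that also had OF1. Of the lists tested, 16 of 28 G2/M mitotic genes and 3 of 10 histone genes rose. HIST1H2AC rose 2.6-fold (log2 change 1.38 ± 0.11, SE), from 4.34 ± 0.54 to 11.3 ± 1.3 CPM (SD, n = 3 each), HIST1H2BK 1.73-fold and HIST1H2BD 1.79-fold. CDK1 rose 1.39-fold and HMMR 1.56-fold (adjusted p = 7.84e-06 for both). Of 28 G2/M mitotic genes 16 rose and 12 did not pass, with 18 risen and 1 fallen when adjusted over the list alone (median 0.17, camera adjusted p = 1.45e-12, adjusted p = 0.000918 with an estimated correlation). Of 26 licensing and firing genes ORC1 rose (0.20 ± 0.04), with 7 risen when adjusted over the list alone (median 0.09, camera adjusted p = 1.57e-05, adjusted p = 0.0124 with an estimated correlation). Of 12 genes of CDC7, DBF4, the MCM helicase and partners 6 rose, also when adjusted over the list alone, among them MCM3 (0.36 ± 0.03), MCM7 (0.21 ± 0.03) and MCM2 (0.18 ± 0.03; list median 0.11, camera adjusted p = 0.000232, and adjusted p = 0.0973 with an estimated correlation). The 10 histone genes had a median of 0.25 with 3 risen, also when adjusted over the list alone (camera adjusted p = 0.000964, and adjusted p = 0.0567 with an estimated correlation). Among the better expressed genes, GCOM1 and LAPTM5 were the other large rises, and the muscle genes MYBPH, ACTA1, TNNI1, MYH8 and MYLPF the largest falls, from -2.97 to -2.74. Of 34 muscle fibre genes 26 fell. Of 22 matrix genes 13 fell, with 15 fallen when adjusted over the list alone (median -0.38, camera adjusted p = 1.25e-07, and adjusted p = 0.255 with an estimated correlation). On the log2 CPM scale their median was -0.17 with replicate 1 alone, against -0.39. In all, 429 genes rose and 416 fell (845 of 15353). The count was 10 with muscle scores as covariates, which ended the calls of HIST1H2BD, MCM2, MCM3, MCM7, ORC1, GCOM1, LAPTM5 and the 5 muscle genes, 53 with replicate 1 alone for the combination, which ended the same calls but that of MCM3, 120 in the 6 libraries alone and 9 against a 1.2-fold change. It was 384, 291 or 382 without OF1 replicate 1, 2 or 3, and 2227, 212 or 370 without combination replicate 1, 2 or 3, with LAPTM5 and the 5 muscle genes not called without OF1 replicate 2 or combination replicate 2. LAPTM5 was not called without OF1 replicate 1 or combination replicate 3 either, MYBPH, ACTA1 and TNNI1 not without OF1 or combination replicate 3, and MYLPF and ORC1 not without OF1 replicate 3. Log2 changes with replicate 1 alone were 0.97 for HIST1H2BD, 0.75 for LAPTM5, 1.82 for GCOM1 and 0.20 for ORC1, and with the covariates 0.76, 1.16, 1.67 and 0.21, while the 5 muscle genes lay at -2.06 to -1.87 and -0.22 to 0.35. MCM2, MCM3 and MCM7 lay at 0.15, 0.3 and 0.17 with the covariates, and MCM2 and MCM7 at 0.13 and 0.14 with replicate 1 alone.

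The XL413 effect without and with OF1 likewise shared no library. Of the 430 genes called for XL413 against DMSO, 387 (90%) had the same direction in the combination against OF1, against 63.2% of all genes (50.2% simulated). Both called 90 genes as risen, where independent lists would share 5.4, and 56 as fallen, where they would share 6.4. Across genes r was -0.03 and rho 0.27.

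Comparisons against the same DMSO libraries overlapped as well. XL413 and the combination shared 125 risen and 150 fallen genes (10.9 and 12 for independent lists), and OF1 and the combination 70 and 66 (5 and 4.4). XL413 and OF1 shared 6 risen and 16 fallen genes (1.1 and 1.3) and called 7 in opposite directions. Their correlation across genes was 0.43, against 0.5 in simulations of unchanged groups, with a covariance of 0.0202 against 0.0172. The correlation was 0.29 for either inhibitor with the combination, against 0.5 simulated, with covariances of 0.0181 against 0.0174 for XL413 and 0.0177 against 0.0177 for OF1. With 3 DMSO libraries these could not be divided into parts of at least 2, and part of the excess overlap may come from the shared libraries. Since the simulations drew genes independently, nothing is concluded from the differences to the simulated values.

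Non-additivity was the departure of the combination from the sum of both single log2 changes. ATF4 targets lay above that sum, and NF-kB targets and secreted factors below it, as lists. The 21 ATF4 targets had a median departure of 0.18, with 13 above and 1 below when adjusted over the list alone (camera adjusted p = 6.78e-12, adjusted p = 0.0151 with an estimated correlation). The 24 NF-kB targets and secreted factors had a median of -0.17, with 7 below when adjusted over the list alone (camera adjusted p = 7.02e-08, adjusted p = 0.0377 with an estimated correlation). The 28 G2/M mitotic genes had a median of 0.06 (camera adjusted p = 0.00129, adjusted p = 0.0377 with an estimated correlation). As single genes, edgeR called 0 of 15353, with 1566 at an unadjusted p under 0.05. DESeq2 called 109 and limma-voom 0. The genes of smallest p were NREP (-0.43 ± 0.06, SE, adjusted p = 0.0797), the smooth muscle actin ACTA2 (-0.85 ± 0.14, adjusted p = 0.0869) and COL1A1 (-1.83 ± 0.31, adjusted p = 0.0869). Beside these, the muscle fibre genes had a median of -2.79. Without combination replicate 1 the count was 362, without DMSO replicate 1 or 3 it was 1 or 6, and without XL413 replicate 3 it was 1. Without the low-count filter it was 132.

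Averaged over cells with and without OF1, XL413 raised 981 genes and lowered 864. HMMR (0.60 ± 0.03, SE, n = 6 against 6), CDK1 (0.46 ± 0.02) and HIST1H2AC (1.13 ± 0.08) rose, and ICAM1 and CXCL1 both by 0.30 ± 0.03. Of 26 licensing and firing genes 6 rose, ORC1, GINS2 and PCNA among them, with 10 risen when adjusted over the list alone (median 0.07, camera adjusted p = 0.000144, adjusted p = 0.025 with an estimated correlation). Averaged over cells with and without XL413, OF1 raised 339 genes and lowered 420. ASNS rose by 0.75 ± 0.02 and SLC7A11 by 0.61 ± 0.05, and MMP3 fell by 0.92 ± 0.07. Of 21 ATF4 targets 17 rose, with 18 risen when adjusted over the list alone (median 0.24, camera adjusted p = 4.15e-29, adjusted p = 0.000592 with an estimated correlation). Of 20 cholesterol synthesis genes 6 fell, with 9 fallen when adjusted over the list alone (median -0.08, camera adjusted p = 0.000315, adjusted p = 0.0293 with an estimated correlation). Among them were DHCR7 (-0.18 ± 0.04) and STARD4 (-0.37 ± 0.08), the latter not called with replicate 1 alone for the combination, at a log2 change of -0.29. GINS2 and PCNA were not called with muscle scores as covariates (log2 changes 0.18 and 0.12) or without DMSO replicate 2, nor PCNA without XL413 replicate 3. With replicate 1 alone for the combination GINS2 was not called either, at a log2 change of 0.13 against 0.17 with all 3 replicates. Beside these, muscle fibre genes had a median of -0.84 and fibroblast markers -0.38 in the average XL413 effect, and -0.75 and -0.44 in the average OF1 effect. The average XL413 count of 1845 was 680 with muscle scores as covariates, 951 with replicate 1 alone for the combination and 11 against a 1.2-fold change, and the average OF1 count of 759 was 21 against that change. Leaving out DMSO replicate 2 or 3, XL413 replicate 2 or 3, OF1 replicate 1 or combination replicate 1 gave 1051, 1137, 1050, 1161, 1198 or 2903 genes for XL413, while for OF1 DMSO replicates 2 and 3 gave 412 and 446, XL413 replicates 1 and 2 gave 412 and 481, and OF1 replicate 2 gave 427. Over all 4 groups 1941 genes differed, with 1046 or 1248 without DMSO replicate 2 or 3, 1132 without XL413 replicate 2, 1203 without OF1 replicate 2, and 3102 or 1175 without combination replicate 1 or 2.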

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

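The counts over other splits of the libraries were planned, and the tests of muscle transcripts, of replicate 1 alone and of GC content and length were chosen after the results were seen.

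The departure of the combination from the sum of the single effects was tested for each gene list, and 10 lists passed with the preset correlation. ATF4 targets had a median of 0.18, NF-kB targets and secreted factors -0.17 and G2/M mitotic genes 0.06, and these passed with an estimated correlation as well. TGF-beta and extracellular matrix genes had a median of -0.52 (adjusted p = 0.114 with an estimated correlation) and fibroblast markers -1.11 (adjusted p = 0.211). With replicate 1 alone for the combination, on the log2 CPM scale, these were -0.21 and -0.46, against -0.52 and -1.28 with all 3 replicates. HOX cluster genes had -0.13 and origin licensing genes 0.05 (adjusted p = 0.114 for both with an estimated correlation). MYC and ribosome biogenesis genes had 0.06 and the CDC7 and MCM helicase list 0.09 (adjusted p = 0.211 for both). Bromodomain reader genes had 0.07 (adjusted p = 0.337).

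ATF4 targets lay above the sum of the single effects as a list, by a median of 0.18 on the log2 scale. Varying muscle RNA is argued against as the whole source, since with muscle scores as covariates the median was 0.15 (camera adjusted p = 7.11e-08). With replicate 1 alone for the combination the median was 0.14, a value of a single library. GC and length bias is argued against too, since with those trends removed the median was 0.17 (camera adjusted p = 5.11e-13). The covariate and trend tests used the preset correlation and were not repeated with an estimated one, so they rest mainly on the kept medians. A greater response of these genes to OF1 in cells that also have XL413 may be a biological source. The same departure can be read as a fall with XL413 alone (median -0.12) that was absent beside OF1. There the combination lay at a median of 0.05 against OF1. Either reading stays a hypothesis found and tested on the same libraries.

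Muscle transcripts varied among the libraries and were lowest in combination replicates 2 and 3, and a candidate source is RNA of skeletal muscle mixed in in varying amounts. The 34 muscle fibre genes, listed after such genes were seen to vary, had a mean pairwise correlation of within-group deviations of 0.77 (0.52 for the 8 that passed in no comparison). A muscle programme of the cells would also give this, so the 2 cannot be told apart, and other sources were not tested. Of 13 muscle progenitor genes (median -1.08) 3 fell and 1, MSC, rose (log2 change 0.3) in the combination against DMSO. VGLL2 of that list ranged only from 3.62 to 5.05 CPM over the libraries. Whether there was a single source of fixed composition (the fibre minus the progenitor score ranged over 1.58) stays open, as does a treatment effect on muscle genes (permutation p = 0.026 for the fibre and 0.058 for the progenitor score, 100000 permutations), since combination replicate 1 lay within the range of the other groups. Of the 52 genes over 2-fold lower in the combination than in DMSO, 9 were muscle list genes. With muscle scores as covariates 5.8% of the 52 were still called, and their median went from -1.41 (SD over genes 1.09) to -0.64 (SD 1.14) with 52 below 0. With replicate 1 alone the median was -0.81 with 52 below 0. That replicate's fibre score of 0.38 lay at the low end of the DMSO range (0.35 to 1.89). The 52 genes were also chosen as fallen with that replicate included, so lower muscle RNA as their source stays open. Of the 726 genes that fell less than 2-fold 27.3% were still called with the median at -0.21 before and -0.22 after, which argues against muscle RNA as the whole source of those falls. These genes too were chosen as fallen on the same libraries, so part of the kept median may come from that choice.

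G2/M mitotic genes were higher with XL413 than with DMSO as a list, by a mean of 0.13. GC and length bias between libraries is argued against, since with those trends removed the mean was 0.13 (camera adjusted p = 9.69e-08, with the preset correlation only). A change in the share of cells in G2 or mitosis may underlie it, and was not tested.

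In the average effects and the overall test no other drawn split gave as many genes as the real one. This argues against a chance assignment of the libraries. Such splits cannot separate a treatment effect from handling shared by the libraries of a group. For the average XL413 effect 1 of 100 splits gave as many genes (1845, highest other 326), for the average OF1 effect 1 of 100 (759, highest other 211), and for any difference among the 4 groups 1 of 100 (1941, highest other 84). The 10 splits of 6 libraries are too few for a share under 0.05. There the real and highest other counts were 430 and 1 for XL413 against DMSO, 176 and 0 for OF1 against DMSO, 1645 and 0 for the combination against DMSO, 524 and 0 against XL413, and 845 and 0 against OF1. In each of these 1 split, the real one, gave as many genes. For non-additivity edgeR called 0 genes (1566 at an unadjusted p under 0.05, DESeq2 109, limma-voom 0), so 100 of 100 splits gave as many. Another split gave 645. These splits mixed the libraries of all 4 groups, so a split can line up with the treatments themselves. Whether that or another structure of the samples gave the 645 was not tested.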

How the results depend on the processing

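The muscle scores, replicate 1 alone and GC and length offsets were tests chosen after the results were seen; the other settings were planned. The cause of the changes below was not tested. Some settings also differ from the main fit in the number of libraries, the bar or the number of coefficients.

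Against a 1.2-fold change, a higher bar, 5 genes were called for XL413 against DMSO, 5 for OF1 against DMSO, 34 for the combination against DMSO, 33 against XL413, 9 against OF1, 11 for the average XL413 and 21 for the average OF1 effect. DESeq2 called 357 genes for OF1 against DMSO and 109 for non-additivity. With the 6 libraries compared alone 1394 genes were called for XL413 and 878 for the combination against DMSO, and 120 for the combination against OF1. Without a low-count filter 132 were called for non-additivity. With muscle scores as covariates 421 were called for the combination against DMSO, 39 against XL413, 10 against OF1 and 680 for the average XL413 effect. With replicate 1 alone these were 857, 155, 53 and 951, and 1 for non-additivity. With GC and length offsets 801 were called for XL413 against DMSO, 812 for the combination against XL413 and 15 for non-additivity, and with the replicate block added 809 for XL413 against DMSO, 1288 for the combination against OF1 and 11 for non-additivity.

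Leaving out each library in turn gave 86 to 287 genes for XL413 against DMSO, 42 to 79 for OF1 against DMSO, 728 to 2113 for the combination against DMSO, 168 to 828 against XL413, 212 to 2227 against OF1, 0 to 362 for non-additivity, 1050 to 2903 for the average XL413 effect, 412 to 1117 for the average OF1 effect and 1046 to 3102 for any difference. Most of the libraries concerned are named with each comparison. The 2113 for the combination against DMSO came without combination replicate 1, and the 1117 for the average OF1 effect without combination replicate 3. Fold-change correlations ranged from -0.11 to 0.05 for the OF1 effect without and with XL413, -0.1 to 0.05 for the XL413 effect without and with OF1, 0.36 to 0.57 for XL413 and OF1, 0.22 to 0.41 for XL413 and the combination, and 0.2 to 0.4 for OF1 and the combination. With replicate 1 alone they were 0.07, 0.03 and 0.37 for the OF1 effect, the XL413 effect, and OF1 and the combination. List tests were not run leaving out libraries.

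With an estimated correlation 4 lists were called for XL413 against DMSO, 1 for OF1 against DMSO, 4 for the combination against DMSO, 1 against XL413, 2 against OF1, 3 for non-additivity, 4 for the average XL413 and 4 for the average OF1 effect. With muscle scores 8 were called for the combination against XL413 and 5 for non-additivity, and with replicate 1 alone 8 against XL413. For the average OF1 effect fry called 14, and GC and length offsets 17, also with the replicate block. The ribosomal protein list turned direction in the combination against XL413 with muscle scores (adjusted p = 0.939) and replicate 1 alone (adjusted p = 0.226), and in the average OF1 effect with replicate 1 alone (adjusted p = 0.75). The G2/M list turned in the average OF1 effect with GC and length offsets (adjusted p = 0.0323, or 0.0349 with the replicate block). With muscle scores the log2 change turned to 0.31 for MYBPH and 0.24 for TNNT3 against XL413, and to 0.31 for MYBPH, 0.35 for ACTA1 and 0.01 for FTH1 against OF1.

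Of 9604 alternatives for 471 named gene results 7838 kept a call with its direction or stayed without a call, 1745 lost the call, 16 gained it and 5 turned. Direction was not compared where a result stayed without a call. With the replicate number as a block 361 genes were called for XL413 against DMSO, 126 for OF1 against DMSO, 1573 for the combination against DMSO, 476 against XL413, 850 against OF1, 2 for non-additivity, 1845 and 670 for the average XL413 and OF1 effects, and 1860 for any difference. The 18 same-number pairs had correlations of deviations from -0.161 to 0.199, 1 of them over 0.1, and 0 libraries correlated best with their own number in every other group, so the numbers were not taken to pair libraries. At this depth the simulated recovery for XL413 against DMSO was 70.2% at 1.3-fold among genes with a mean of at least 1 CPM, which limits smaller changes.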

Other observations

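The list tests in this part were fixed before the data were examined, and the muscle covariates were chosen after the results were seen.

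Some genes of translation and respiration rose with XL413, as single genes and in lists that lost their calls with an estimated correlation. In the average XL413 effect (n = 6 libraries against 6) 7 of 25 cytosolic ribosomal protein genes rose, RPS6 among them (0.15 ± 0.04 on the log2 scale, SE), with 21 risen when adjusted over the list alone (median 0.12, camera adjusted p = 1.72e-06, and adjusted p = 0.521 with an estimated correlation). Of 22 oxidative phosphorylation genes 11 rose, including the cytochrome oxidase subunits COX5B (0.26 ± 0.06) and COX6C (0.32 ± 0.07), with 13 risen and 1 fallen when adjusted over the list alone (median 0.12, camera adjusted p = 0.000126, and adjusted p = 0.521 with an estimated correlation). With replicate 1 alone for the combination, on the log2 CPM scale, the median was 0.06 for ribosomal protein and 0.08 for oxidative phosphorylation genes. With all 3 replicates it was 0.12 for each list. Bromodomain reader genes had 1 risen and 6 fallen of 22, with 2 and 8 when adjusted over the list alone (median -0.06, camera adjusted p = 0.0187, and adjusted p = 0.346 with an estimated correlation). BRD8 rose by 0.18 ± 0.03, and BRD2 and BRD3, readers of acetylated histones, fell by 0.12 ± 0.02 and 0.20 ± 0.04. BRPF1, a target of OF1, fell by 0.11 ± 0.03 with XL413 on average. With muscle scores as covariates RPS6, COX5B, COX6C and BRPF1 lost their calls, at log2 changes of 0.13, 0.20, 0.29 and -0.10. RPS6 and BRPF1 also lost them without DMSO replicate 2 or 3, XL413 replicate 3 or OF1 replicate 1, RPS6 without XL413 replicate 2, and BRPF1 without combination replicate 2. With replicate 1 alone for the combination RPS6 and BRPF1 lost them too, at log2 changes of 0.11 and -0.09.

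In the combination against DMSO, of 21 homologous recombination and Fanconi genes 6 rose, FANCD2 (0.21 ± 0.04) among them, with 7 risen when adjusted over the list alone (median 0.09, camera adjusted p = 0.000986, and adjusted p = 0.156 with an estimated correlation). FANCD2 lost its call without DMSO replicate 2. MT2A, a metal-binding metallothionein, rose by 0.55 ± 0.07, and PMAIP1, a pro-apoptotic p53 target, by 0.33 ± 0.04. The spermidine synthase SRM fell by 0.31 ± 0.04. In the average OF1 effect CA9 fell by 1.47 ± 0.18, and 4 of 23 hypoxia genes fell, with 7 fallen when adjusted over the list alone (median -0.03, camera adjusted p = 0.00553, and adjusted p = 0.154 with an estimated correlation).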
